A study of Mus musculus with 8 samples.

How the data were processed

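RNA sequencing was done on 8 libraries of BaF3 cells, a mouse pro-B cell line that normally depends on interleukin-3, carrying Jak2 with the V617F change that activates the kinase. The cells expressed a non-targeting short hairpin (shNT, 4 libraries) or one of 2 hairpins against Ybx1 (sh1Ybx1 and sh2Ybx1, 2 libraries each). Per the labels' protocols, total RNA was extracted with a column kit, polyadenylated RNA was isolated on magnetic beads and libraries were sequenced on a NextSeq 500. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. Groups were taken from the sample titles and genotype labels.

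The deposited gene table holds raw counts per gene and library for 13588 genes, with the authors' log2 fold change, p-value and adjusted p of knockdown against control. The submitters' processing notes name STAR, featureCounts, limma and RSEM, without versions or roles, and the builds GRCm38 and mm9. The deposited TPM and FPKM values per gene and per transcript have identifier columns named as RSEM names them, per the file headers. The authors' splicing table gives per event a class, coordinates, a difference in percent spliced in (delta PSI, from -1 to 1) and a p-value that is not adjusted. Its z value, a score per event deposited by the authors, was not used in any test. The program that called the events is not given in the sources used here. The authors' exon table gives counts per exon bin, a log2 fold change of relative use and an adjusted p. A deposited list of pathways among spliced genes gives log10 p and log10 q per term. No setting for strand is given in the sources used here, so reads of a gene and of a transcript overlapping it on the other strand may not be separated.

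The plan fixed before the data were examined named limma on TPM as the test, and edgeR in its place if whole-number counts were deposited. They were, so edgeR's quasi-likelihood test was used (edgeR 4.0.16, R 4.3.3) with TMM scaling, filterByExpr, and 1 fit of 3 group means over all 8 libraries. It left 13552 genes. Contrasts were the mean of both hairpins against shNT, each hairpin against shNT, and sh1Ybx1 against sh2Ybx1, with Benjamini-Hochberg adjusted p under 0.05 and no fold minimum. Levels are CPM after TMM scaling. Standard errors are on the log2 scale. The edgeR test gives none, so each was derived as the size of the log2 fold change over the square root of the test's F statistic. They are approximate, the more so for genes with few counts.

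Total counts ran from 22779437 to 37549926 per library. On counts simulated from these libraries, edgeR called 2 of 67 genes changed 1.5-fold, 36 of 67 changed 2-fold and 61 of 66 changed 4-fold for both hairpins against shNT, with 8 false calls among 13352 unchanged genes. For sh1Ybx1 alone it called 1 of 67, 10 of 67 and 53 of 66, with 3 false calls, and for sh2Ybx1 alone 0 of 67, 13 of 67 and 49 of 66, with 7 false calls. The simulation gave each gene 1 spread for all 8 libraries. The observed biological coefficient of variation was 0.323 in shNT, 0.0760 in sh1Ybx1 and 0.0616 in sh2Ybx1, so these rates may not hold for the real libraries.

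The 28 gene lists were fixed with the plan: MAPK ERK pathway, ERK response, JAK STAT signalling, STAT5 targets, apoptosis BCL2 family, p53 targets, cell cycle, spliceosome and SR proteins, hnRNP and other splicing regulators, cold shock domain and YBX1 partners, MYC targets, ribosomal proteins, translation factors, unfolded protein and integrated stress response, interferon response, cholesterol synthesis, glycolysis and hypoxia, nuclear oxidative phosphorylation, B lymphoid, myeloid, mast cell, erythroid and megakaryocyte, T and NK cell, fibroblast, nonsense mediated decay, replication-dependent histones, mitochondrial-genome mRNAs, and small structured and snoRNA host RNAs. The last 3 report on RNA quality. Each was tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists. An estimated correlation and fry, which tests whether a list's genes move on balance in 1 direction without comparing them with other genes, were alternatives. On simulated counts camera called 1 of 1 shifted list and 0 of 27 unchanged lists. Genes were drawn there independently of each other, so this does not show how camera does on lists of correlated genes.

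Genes named in the text follow a rule fixed at the same time. It takes Ybx1, then the 8 highest and 8 lowest log2 fold changes among called genes with a mean TPM of 5 or more and every knockdown library beyond every shNT library. Symbols that are only numbered or bare identifiers are left out. It adds up to 4 members per list by smallest adjusted p, the 5 highest and 5 lowest genes between hairpins, and 5 genes called with 1 hairpin and of opposite sign with the other, by smallest p of the difference. For isoform use it takes 8 transcripts past the threshold, of which there were none. A gene that the rule takes is not reported here. For the splicing table it takes 2 events per class and up to 4 per list, by smallest adjusted p, for the MAPK ERK, JAK STAT, BCL2 and spliceosome lists.

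Relative isoform use was tested with limma on log2((transcript TPM + 0.5) / (other transcripts' TPM of the gene + 0.5)), for transcripts of genes with a mean TPM of 5 or more and a mean share from 5 to 95 percent. That left 26752 transcripts of 7504 genes. In simulations for both hairpins this test called 0 of 50 transcripts shifted by 2 log2 units, 2 of 50 shifted by 4 and 9 of 50 shifted by 6, and 0 of 26552 unchanged ones. For each single hairpin it called 0 of 50 at every size.

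The authors' splicing events were counted by class and sign at p under 0.05, with values of delta PSI within 1e-09 of 0 set to 0 (3234 events). Benjamini-Hochberg adjustment of the event p-values was added. Events start and end as the authors' table gives them. Of 4479 retained introns, 3384 (75.55%) match an intron of the GRCm38 GENCODE M21 annotation to the base. That annotation also gave gene positions and the placing of each exon bin in exons or introns, and no read counts. Lists were tested for spliced genes with two-sided Fisher's exact tests against tested genes with at least 2 transcripts, and, as an alternative chosen after seeing the data, against genes with an event in the table. On the first background, 1 of 500 list tests on random gene sets and 1 of 1 planted list passed.

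Alternatives covered pseudocounts, filters, TPM and FPKM in place of counts, scaling, moderation, replicate blocks, the samples in a fit, thresholds and leaving out each library. Limma on log2(TPM + 1), DESeq2 1.42.0, protein-coding genes only, the adjusted event p, events without retained introns and the narrower background were added after the data were seen. Pairwise chi-square statistics per gene between replicates ran from 10.64 to 349.9, so no library pair agreed within sampling noise. Python 3.11.15 with pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the splicing tables and figures. Gene FPKM entered as an alternative and in a check for genomic DNA, and transcript FPKM only as an alternative. Gene symbols and gene types are those of the deposited gene table.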

Results

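The series examined mRNA processing and splicing after knockdown of Ybx1, which encodes a cold shock domain protein that binds RNA and DNA, in BaF3 cells with Jak2 V617F. Libraries from 4 shNT, 2 sh1Ybx1 and 2 sh2Ybx1 samples were compared. Total counts over the listed genes were 30145813, 36035387, 37549926 and 26093847 for shNT replicates 1 to 4, 22779437 and 23217610 for sh1Ybx1, and 23041869 and 26464953 for sh2Ybx1. The first principal component held 50.87% of the variance and separated the knockdown libraries from shNT. The second held 25.36% and set shNT replicate 4 apart from the other 7 libraries. Biological coefficients of variation were 0.323 among shNT libraries, 0.205 without shNT replicate 4, 0.0760 for sh1Ybx1 and 0.0616 for sh2Ybx1.

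Ybx1 transcript (ENSMUSG00000028639, chromosome 4, 119277981 to 119294604, minus strand, GRCm38) fell in every knockdown library. It was at 1731, 1631, 1607 and 1731 CPM (counts scaled to the normalised library size) in shNT (1675 ± 65.4, SD, n = 4), 130 and 143 in sh1Ybx1, and 178 and 217 in sh2Ybx1. The level left was 8.14% of shNT with sh1Ybx1 and 11.8% with sh2Ybx1. The log2 fold change for both hairpins was -3.35 (SE 0.139, edgeR adjusted p = 3.39e-05). An exact permutation test of the 4 knockdown against the 4 shNT libraries (two-sided, 70 arrangements) gave p = 0.0286, the smallest these sample sizes allow. The hairpins differed by -0.54 (SE 0.18, edgeR adjusted p = 0.225), which did not pass.

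**Figure D1:**
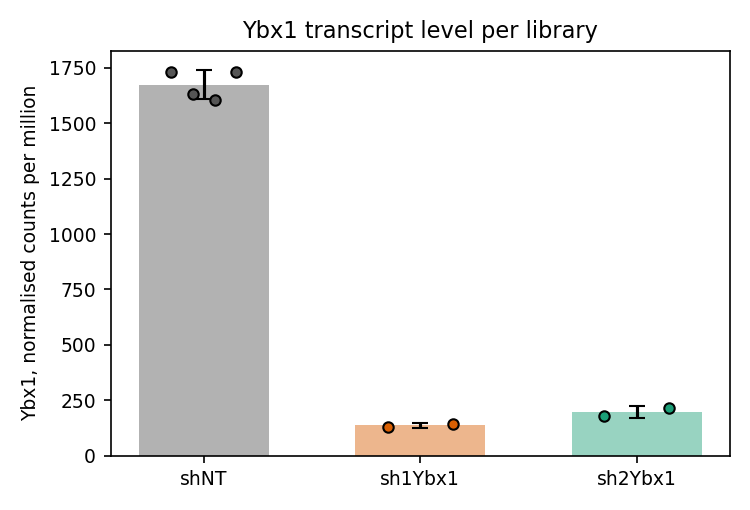
Ybx1 level in each library, in CPM, for shNT, sh1Ybx1 and sh2Ybx1. Bars are group means, error bars are SD and points are libraries; the 4 knockdown libraries lie between 130 and 217 and the 4 shNT libraries between 1607 and 1731.

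The comparison of both hairpins with shNT asked which transcripts change when Ybx1 is lowered. The lists of glycolysis and hypoxia, the unfolded protein response, cholesterol synthesis and translation factors passed camera, a gene set test, as lower, and those of mitochondrial-genome mRNAs and myeloid genes as higher, the myeloid list with sh1Ybx1 and not with sh2Ybx1 when each was taken alone. With an estimated correlation the unfolded protein list kept its call (adjusted p = 0.0432) and the other 5 did not (adjusted p = 0.409 to 0.497). Of 13552 genes tested, 2001 were higher and 1922 lower (3923 in all, edgeR adjusted p under 0.05), and 5734 had an unadjusted p under 0.05. Among the called genes 1215 rose and 568 fell at least 2-fold. Without shNT replicate 4 the count was 6795. It was 1296 and 2009 without sh1Ybx1 replicate 1 or 2, and 1272 and 1853 without sh2Ybx1 replicate 1 or 2. With limma on log2(TPM + 1), chosen after seeing the data, 370 genes passed, 87 higher and 283 lower, and on FPKM 301 passed, 157 higher and 144 lower.

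Of the 8 genes that rose most under the naming rule, Olr1, a scavenger receptor for oxidised lipoprotein, rose by a log2 fold change of 3.86 (SE 0.519, adjusted p = 0.00302), from 0.891 ± 0.604 (SD, n = 4) to 16.8 ± 12.03 (SD, n = 4) CPM. The chemokine Ccl6 rose by 3.70 (SE 0.394), the adhesion molecule L1cam by 3.11 (SE 0.438), the signalling adaptor Tyrobp by 2.82 (SE 0.411) and the metalloprotease Adam8 by 2.70 (SE 0.31). Cpa3, a mast cell carboxypeptidase, rose by 2.77 (SE 0.643), and mt-Rnr2, the large mitochondrial ribosomal RNA, by 2.77 (SE 0.357). Rps19-ps4, a pseudogene that shares sequence with the Rps19 family, had a value of 2.67 (SE 0.555) at 0.168 CPM in shNT and 1.03 in the knockdown libraries, and its sign turned to -0.18 with limma on log2(TPM + 1), so it is uncertain. In the edgeR fit the adjusted p of these 8 genes lay between 0.00151 and 0.0155. The call for Cpa3 was lost without sh1Ybx1 replicate 1 or sh2Ybx1 replicate 1 (log2 fold change 2.41 to 3.36 over all libraries left out in turn).

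Of the 8 genes that fell most, Ybx1 was one, and 5 belong to the glycolysis and hypoxia list. Cox6a2, a subunit of cytochrome oxidase, fell (log2 fold change -4.17, SE 0.891, edgeR adjusted p = 0.0119), from 12.4 ± 14.4 to 0.685 ± 0.209 CPM (SD, n = 4 each). So did the hypoxia-induced gene Ankrd37 (-3.83, SE 0.812), the mitophagy receptor Bnip3 (-3.39, SE 0.47), Ndrg1 (-3.22, SE 0.657), the oxidoreductase Ero1l (-3.15, SE 0.578) and Pdk1, a kinase that inhibits pyruvate dehydrogenase (-3.08, SE 0.394). The metallothionein Mt2 fell (-3.62, SE 1.02, edgeR adjusted p = 0.0308), but its shNT level was 1130 ± 1738 (SD, n = 4), and without shNT replicate 4 the log2 fold change was -1.54. The calls for Cox6a2, Ankrd37 and Mt2 were lost whichever knockdown library was left out, and that for Ndrg1 without sh1Ybx1 replicate 1 or sh2Ybx1 replicate 1.

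Among the 28 lists, 12 passed camera for both hairpins, 4 of them higher and 8 lower. With an estimated correlation 1 passed, the unfolded protein and integrated stress response list. In the glycolysis and hypoxia list 25 of 33 tested members fell and 0 rose, with 27 lower when adjusted over the list alone. The median log2 fold change was -1.68 (camera adjusted p = 2.83e-16, adjusted p = 0.409 with an estimated correlation). Phosphofructokinase Pfkl (-2.33, SE 0.219), triosephosphate isomerase Tpi1 (-2.01, SE 0.194), enolase Eno1 (-1.90, SE 0.194) and lactate dehydrogenase Ldha (-1.80, SE 0.175) fell, each with an edgeR adjusted p between 0.00124 and 0.0014. The mean level of the list, as log2(CPM + 1), was 7.94, 7.61, 7.23 and 8.58 in shNT replicates 1 to 4, 6.47 and 6.52 in sh1Ybx1, and 6.26 and 6.28 in sh2Ybx1. The shNT library that stood apart thus held the highest level of these genes, and the median without it was -1.31.

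**Figure D2:**
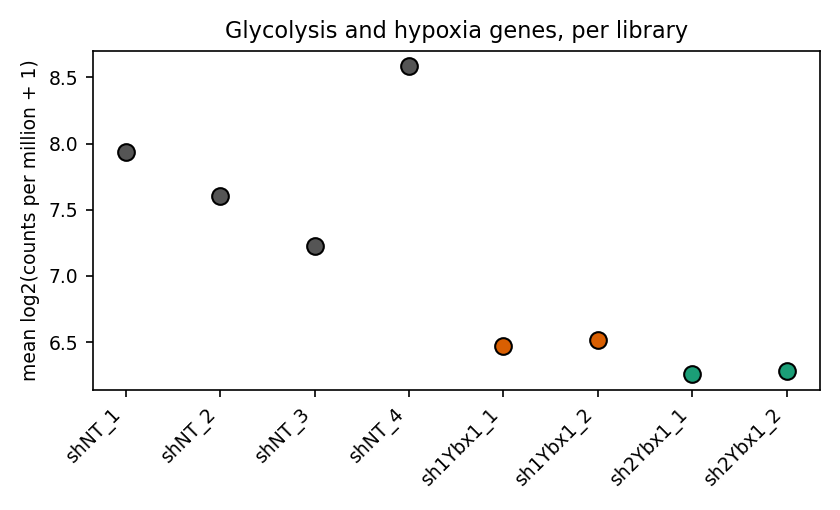
Mean level of the glycolysis and hypoxia list in each library, as log2(CPM + 1) averaged over 33 genes. Each point is a library; the 4 shNT libraries lie between 7.23 and 8.58 and the 4 knockdown libraries between 6.26 and 6.52.

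In the unfolded protein and integrated stress response list 21 of 25 members fell and 0 rose, with 22 lower over the list alone. The median was -1.17 (camera adjusted p = 1.38e-13, adjusted p = 0.0432 with an estimated correlation). The transcription factors Xbp1 (-1.36, SE 0.138) and Atf4 (-1.13, SE 0.215) fell, as did the chaperone Hsp90b1 (-1.33, SE 0.156) and the disulfide isomerase Pdia6 (-1.38, SE 0.134). In the cholesterol synthesis list 13 of 23 members fell, 15 over the list alone, and 0 rose (median -0.72, and -0.47 on FPKM, camera adjusted p = 6.09e-06, adjusted p = 0.456 with an estimated correlation). They included Srebf2, which encodes a transcription factor of sterol synthesis genes (-0.998, SE 0.135), and the enzymes Nsdhl (-0.999, SE 0.14) and Sqle (-0.88, SE 0.145). The genes named from both lists stayed past the threshold when each library was left out in turn.

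Among lists of RNA-binding proteins, of 31 hnRNP and other splicing regulators 13 fell and 2 rose, the same counts over the list alone (median -0.41, camera adjusted p = 0.00148, adjusted p = 0.447 with an estimated correlation). Pcbp2 (-1.20, SE 0.191), Ptbp3 (-1.14, SE 0.149) and Hnrnpa1 (-0.92, SE 0.125) fell, and Hnrnpu rose (0.67, SE 0.111), although Hnrnpu was at -0.44 with limma on log2(TPM + 1) and did not pass there. In the cold shock domain and YBX1 partner list 6 of 12 fell, Ybx1 itself included, and 7 over the list alone (median -0.45, camera adjusted p = 2.98e-05, adjusted p = 0.215 with an estimated correlation). The fall of Ybx1, the knocked-down gene, counts in that test, and the list was not tested without it. Of 28 translation factors 12 fell and 1 rose, with 14 and 1 over the list alone (median -0.49, camera adjusted p = 0.00122, adjusted p = 0.409 with an estimated correlation), among them Eif3c (-1.25, SE 0.189) and Eif4b (-1.15, SE 0.188). In the spliceosome and SR protein list 6 of 41 fell and 1 rose, 2 and 1 over the list alone (median -0.08, camera adjusted p = 0.738), with Snrpa at -0.72 (SE 0.119) and Srsf6 at 0.92 (SE 0.167).

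Lists of signalling genes followed. Of 36 MAPK ERK pathway members 7 fell and 2 rose, also over the list alone (median -0.22, camera adjusted p = 0.0317, adjusted p = 0.456 with an estimated correlation). Map2k1, which encodes the kinase MEK1 (-1.55, SE 0.211), the phosphatase gene Ptpn11 (-0.93, SE 0.14) and the kinase gene Mknk1 (-0.92, SE 0.171) fell, and Mapkapk3 rose by 0.49 (SE 0.0993). With sh2Ybx1 alone Mapkapk3 was at 0.09 and did not pass. This list did not pass with sh1Ybx1 alone (median -0.08, camera adjusted p = 0.341), and no longer passed on FPKM (median -0.09) or among genes with a mean TPM of 5 or more (-0.18). Of 24 ERK response genes 9 fell and 0 rose, 14 and 0 over the list alone (median -0.76, and -0.48 on FPKM, camera adjusted p = 0.00148, adjusted p = 0.146 with an estimated correlation), including the ERK phosphatase Dusp4 (-1.98, SE 0.201) and Myc (-0.73, SE 0.145). In the JAK STAT list 5 of 18 fell (median -0.25, camera adjusted p = 0.210), with the kinase gene Jak3 at -0.45 (SE 0.129). Of 13 STAT5 targets 5 fell (median -0.40, camera adjusted p = 0.117), among them the kinase gene Pim2 (-2.93, SE 0.542) and the cyclin gene Ccnd2 (-1.17, SE 0.266). Of 11 BCL2 family members 3 fell and 1 rose (median -0.28, camera adjusted p = 0.123). The antiapoptotic genes Bcl2 (-1.50, SE 0.161), Bcl2l2 (-0.75, SE 0.191) and Bcl2l1 (-0.82, SE 0.261) fell and the proapoptotic gene Bad rose (0.62, SE 0.19). Over each of these last 3 lists alone the counts were the same. The calls for Jak3, Ccnd2, Bcl2l2, Bcl2l1 and Bad were lost whichever knockdown library was left out, that for Jak3 also without shNT replicate 1, and those for Bcl2l1 and Bad also without shNT replicate 1, 2 or 3. Those for Myc and Mapkapk3 were lost without sh1Ybx1 replicate 1 or sh2Ybx1 replicate 1, and that for Mapkapk3 also without sh2Ybx1 replicate 2.

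Among lists of other cell types and of RNA quality, of 19 myeloid and macrophage genes 7 rose and 2 fell, 9 and 2 over the list alone (median 0.58, camera adjusted p = 0.00824, adjusted p = 0.447 with an estimated correlation). With sh1Ybx1 the median was 1.003 (camera adjusted p = 2.06e-06, adjusted p = 0.152 with an estimated correlation), and with sh2Ybx1 it was 0.23 and did not pass (0.696). The integrin gene Itgam rose by 4.34 (SE 0.511), from 0.120 to 4.004 CPM, and the neutrophil protease gene Prtn3 fell (-1.52, SE 0.337). Of 8 mitochondrial-genome mRNAs 6 rose, 7 over the list alone (median 1.20, camera adjusted p = 0.00191, adjusted p = 0.497 with an estimated correlation), with mt-Nd2 at 1.28 (SE 0.266). Of 8 small structured and snoRNA host RNAs 4 rose, also over the list alone (median 0.77, camera adjusted p = 0.0276, adjusted p = 0.456 with an estimated correlation), with the nuclear RNA Malat1 at 2.06 (SE 0.532), and the list did not pass without shNT replicate 3 (median 0.56) or with sh1Ybx1 alone (median 0.93, camera adjusted p = 0.0579). The call for mt-Nd2 was lost without sh2Ybx1 replicate 1, that for Prtn3 without sh1Ybx1 replicate 1 or sh2Ybx1 replicate 1, and that for Malat1 without shNT replicate 1 or 2 or any knockdown library. Of 82 cytosolic ribosomal protein genes 3 rose (Rpl3l, Rps21 and Rps20) and 0 fell, and 0 passed over the list alone (median 0.22, 0.13 with limma on log2(TPM + 1) and 0.33 on FPKM, camera adjusted p = 0.0276, adjusted p = 0.827 with an estimated correlation). That list did not pass with sh1Ybx1 alone (median 0.11, camera adjusted p = 0.448), or without shNT replicate 1 (median 0.12), shNT replicate 3 (0.09) or sh2Ybx1 replicate 1 (0.18). The call for Rpl3l was lost without sh2Ybx1 replicate 1, that for Rps21 without shNT replicate 1 or 3 or any knockdown library, and that for Rps20 without every library but shNT replicate 4. Of 15 replication-dependent histone genes, whose mRNAs lack a poly(A) tail, 4 rose, also over the list alone (median 0.42, camera adjusted p = 0.0947).

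**Figure D3:**
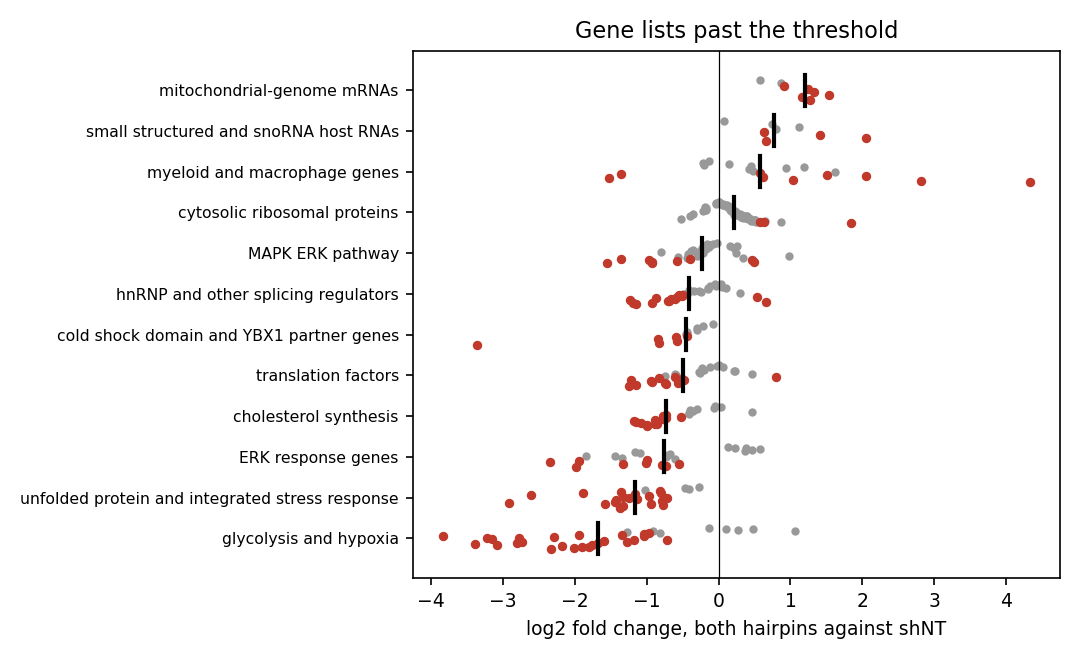
Log2 fold change of both hairpins against shNT for members of the 12 lists that passed camera. Points are genes, red where the edgeR adjusted p was under 0.05 and grey otherwise, and black bars are list medians, from -1.68 for glycolysis and hypoxia to 1.20 for mitochondrial-genome mRNAs.

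Of the lists that did not pass for both hairpins, the remaining 11 follow, each with its camera adjusted p in the last parentheses. With sh1Ybx1 alone 14 lists passed camera, some of which did not pass for both hairpins, and 0 passed with an estimated correlation. The values that follow are for both hairpins unless a hairpin is named. Of 36 cell cycle and DNA replication genes 1 fell, Bub1 (-0.92, SE 0.18) (0.150), and of 22 p53 targets 1 fell, Sesn2 (-1.17, SE 0.272), and 0 over the list alone (0.642). Of 25 MYC targets 4 fell, Ldha, Eno1, Ncl and Hspd1 (0.135). Of 33 interferon response genes 6 fell, including Mx2 at -2.14 (SE 0.508), and 5 over the list alone (0.135). Of 38 nuclear oxidative phosphorylation genes 4 rose and 2 fell, 4 and 1 over the list alone, with Cox4i1 at 0.53 (SE 0.115) and Sdha at -0.56 (SE 0.121) (0.135). Of 8 mast cell genes 4 rose and 1 fell, with the prostaglandin synthase Hpgds at 2.66 (SE 0.41) and the transcription factor Gata2 at -0.91 (SE 0.155) (0.254). Of 6 B lymphoid genes 1 rose, the phosphatase Ptprc (0.86, SE 0.2), and 1 fell, the transcription factor Ikzf1 (-0.73, SE 0.118) (0.684). Of 16 erythroid and megakaryocyte genes 2 fell, the platelet glycoproteins Gp9 (-1.24, SE 0.232) and Gp1ba (-1.10, SE 0.334), and 1 over the list alone (0.446). Of 3 T and NK cell genes 1 fell, Nkg7 (-1.74, SE 0.478) (0.2504). Of 5 fibroblast genes 2 rose, Acta2 (2.25, SE 0.304) and Timp1 (2.15, SE 0.698), and over the list alone 3 rose and 1 fell (0.0814). Acta2 was at 4.71 with sh1Ybx1 and at -0.21 with sh2Ybx1, which did not pass (edgeR adjusted p = 0.725), and neither hairpin alone gave a call for Timp1. Nkg7 was at -3.69 with sh1Ybx1 and at 0.21 with sh2Ybx1, which did not pass, as Ptprc did not with sh2Ybx1 (0.37). Of 16 genes of the nonsense mediated decay list 2 rose, the decay factors Upf3b and Smg5, and 2 fell, Atf4 and Gadd45b (0.694). In the lists with no separate mention, the counts over the list alone were the same. The calls for Sesn2, Mx2, Gp1ba, Nkg7 and Smg5 were lost whichever knockdown library was left out, as was that for Upf3b. Those for Smg5, Nkg7 and Upf3b were also lost without shNT replicate 1, and those for Gp1ba and Upf3b without shNT replicate 3. Calls for Ncl, Sdha, Gadd45b, Hspd1, Cox4i1 and Ptprc were lost without sh1Ybx1 replicate 1 or sh2Ybx1 replicate 1, and that for Bub1 without the latter. That for Hspd1 was also lost without sh1Ybx1 replicate 2, and those for Cox4i1 and Ptprc without sh2Ybx1 replicate 2. The call for Timp1 was lost without every library but shNT replicate 4, without which its log2 fold change was 3.46.

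In several of the authors' gene types outside protein-coding genes more members rose than fell, but of 635 processed pseudogenes 95 rose and 106 fell. Of the others, 122 of 226 TEC genes, a class of transcripts still to be experimentally checked, rose and 3 fell. Their sum rose from 282 ± 24.2 to 525 ± 46.9 CPM (SD, n = 4 each). Of 85 snoRNA genes 54 rose and 0 fell (101 ± 33.6 to 226 ± 33.3 CPM), of 399 antisense genes 130 rose and 10 fell, of 403 lincRNA genes 113 rose and 15 fell, and of 32 sense intronic genes 21 rose and 1 fell. Of 11283 protein-coding genes 1318 rose and 1766 fell. Many of these noncoding genes lie within or opposite other genes, so their reads may not be separable from those of the host.

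Each hairpin was also set against shNT, since a single hairpin can have effects on other targets. With sh1Ybx1 1522 genes rose and 1079 fell (2601 in all), and with sh2Ybx1 1411 rose and 1281 fell (2692 in all, edgeR adjusted p under 0.05 in both). From the glycolysis and hypoxia list, Pdk1 (-3.01 and -3.14) and Bnip3 (-3.09 and -3.69) fell with sh1Ybx1 and sh2Ybx1. The unfolded protein list had a median of -1.10 with sh1Ybx1 and -1.23 with sh2Ybx1, with an estimated-correlation adjusted p of 0.111 and 0.0488. In all 1421 genes were called with both hairpins in the same direction (813 higher, 608 lower) and 12 in opposite directions. Independent lists of these sizes would share 158.5 higher and 102 lower genes. Across genes, which are not independent replicates, the fold changes of the hairpins had a Pearson correlation of 0.785 and a covariance of 0.645. Unchanged groups simulated with shared controls, at 1 spread per gene for all 8 libraries, gave 0.310 and 0.0503. The observed biological coefficient of variation was larger in shNT (0.323) than in sh1Ybx1 (0.0760) and sh2Ybx1 (0.0616). A larger spread in shared controls raises the correlation of unchanged groups, so 0.310 may be too low a value to compare with. With 2 controls per hairpin the correlation was 0.507 to 0.714 and the covariance 0.448 to 0.548 over the 6 assignments. Shared genes ran from 0 to 599 with a median of 0. In each assignment with 0 shared genes a hairpin had 0 calls, so no gene could be shared and the median does not measure sharing. Where both hairpins had calls, 599 genes were shared between 831 calls for sh1Ybx1 and 6260 for sh2Ybx1, and 322 between 6338 and 459. With limma on log2(TPM + 1) 96 genes rose and 107 fell with sh1Ybx1, and 30 rose and 97 fell with sh2Ybx1, and with quantile-normalised TPM 24 rose and 40 fell with sh2Ybx1. The sh1Ybx1 count was 5902 without shNT replicate 4, 156 and 385 without sh1Ybx1 replicate 1 or 2, and 1434 and 1394 without sh2Ybx1 replicate 1 or 2. The sh2Ybx1 count was 5843 without shNT replicate 4, 1786 without shNT replicate 1, 1351 and 1349 without sh1Ybx1 replicate 1 or 2, and 40 and 55 without sh2Ybx1 replicate 1 or 2.

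The direct test between hairpins called 71 genes, 63 higher and 8 lower in sh1Ybx1 than in sh2Ybx1 (1901 at an unadjusted p under 0.05). A fit of the 4 hairpin libraries alone called 5620, 2959 higher and 2661 lower. The iron-binding protein gene Lcn2 was higher by 5.603 on the log2 scale (SE 0.853, edgeR adjusted p = 0.0426), at 19.6 CPM in sh1Ybx1, 0.399 in sh2Ybx1 and 1.40 ± 1.25 in shNT (SD, n = 4). The smooth muscle actin gene Acta2 was higher by 4.91 (SE 0.47, adjusted p = 0.00705), at 91.9 against 3.05 and 3.47 ± 1.51 in shNT (SD, n = 4). Ccl6 was higher by 3.33 (SE 0.527), the lectin gene Clec4e by 2.67 (SE 0.188) and the urokinase receptor gene Plaur by 2.65 (SE 0.372). Lower in sh1Ybx1 were Hemgn (-1.54, SE 0.2), the lymphocyte receptor gene Slamf1 (-1.44, SE 0.234), Frmd6 (-1.37, SE 0.149), the cytokinesis gene Anln (-1.24, SE 0.158) and Plpp2 (-1.22, SE 0.17). The named genes of opposite sign against shNT were called as follows: Clec4e was at 2.05 with sh1Ybx1 and -0.61 with sh2Ybx1, the transcription factor Cebpd at 1.06 and -1.51, the transcriptional inhibitor Id2 at 1.47 and -0.99, and the tropomyosin gene Tpm4 at 1.04 and -0.95. Cpne3 was at 0.06 with sh1Ybx1, which did not pass, and at -1.85 with sh2Ybx1. In the myeloid list 11 of 19 members rose and 2 fell with sh1Ybx1, and 1 rose and 0 fell with sh2Ybx1. The list was higher in sh1Ybx1 (median difference 1.10, camera adjusted p = 2.27e-08, adjusted p = 0.187 with an estimated correlation), and 8 lists in all passed camera and 0 with an estimated correlation. The count of 71 genes changed with the libraries in the fit. It was 19, 24, 39 and 1666 without shNT replicate 1, 2, 3 or 4, which are not part of this contrast. It also fell when any knockdown library was left out. The differences themselves moved less. Over all libraries left out in turn they were 5.51 to 5.72 for Lcn2, 4.76 to 5.05 for Acta2, 3.03 to 3.71 for Ccl6 and -1.66 to -1.43 for Hemgn. The call for Clec4e was lost without sh2Ybx1 replicate 1 or 2, that for Cebpd without sh1Ybx1 replicate 2 or either sh2Ybx1 library, and the other named calls whichever knockdown library was left out. Calls for Lcn2, Ccl6, Plaur, Hemgn, Slamf1, Anln and Plpp2 were also lost without shNT replicate 1, those for Ccl6, Plaur, Hemgn, Slamf1 and Plpp2 without shNT replicate 2, and those for Lcn2, Ccl6, Plaur, Slamf1 and Plpp2 without shNT replicate 3. With quantile-normalised TPM and with limma on log2(TPM + 1), 2 genes were higher and 3 lower, and DESeq2, added after the data were seen, called 794.

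Splicing was the stated question of the series. In the authors' deposited table of 26983 events in 6227 genes, 1928 events had p under 0.05, of which 1459 had a positive and 324 a negative delta PSI and 145 were at 0. Retained introns made up 1057 of these, 988 positive and 8 negative, and 23.6% of the 4479 retained introns passed, against 7.14% of all events. After Benjamini-Hochberg adjustment of the authors' p, 368 events passed, 248 of them retained introns (236 positive, 2 negative). The other classes passed at 6.43% of cassette exons (100 events), 4.38% of alternative last exons (103), 4.33% of alternative first exons (102), 4.31% of mutually exclusive exons (5), 3.65% of complex events (413), 3.52% of alternative 3' splice sites (84) and 2.63% of alternative 5' splice sites (64), against 5% by chance. Retained introns at p under 0.05 were matched to the bins of the authors' exon table that they hold, which gave 81 pairs of intron and bin. An intron with several bins counts in several pairs. In 78 pairs the signs were the same and in 3 the delta PSI was 0. A positive value thus stands for more retention in the knockdown libraries. Noncoding RNA of several classes rose in the same libraries. Weaker selection of polyadenylated RNA stays open for that rise, and it was not tested for the retained introns.

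**Figure D4:**
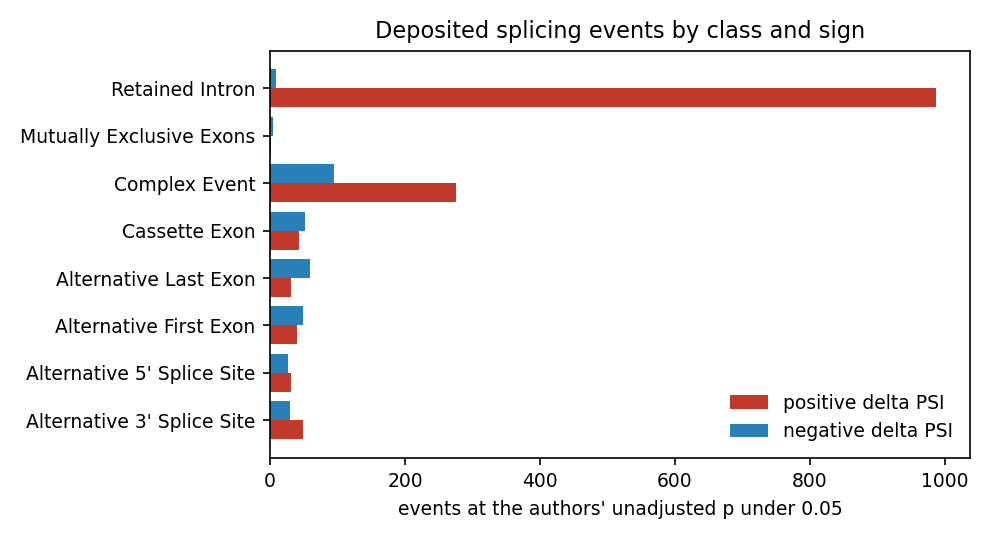
Events of the authors' deposited splicing table with an unadjusted p under 0.05, by class. Bars count events with a positive (red) or negative (blue) delta PSI; retained introns hold 988 positive and 8 negative events.

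Events were named by the smallest p in each class and within lists, with delta PSI as in the authors' deposited table. The retained intron with the smallest p was in Rbck1, a subunit of a ubiquitin ligase complex, on chromosome 2 from 152323332 to 152324267 (delta PSI 0.342, p = 4.12e-11 in the authors' table, adjusted p = 1.11e-06 computed from it). It matches an annotated intron. The next, in the translation initiation factor gene Eif3a on chromosome 19 from 60763264 to 60764004 (0.421), does not match one to the base. A complex event in Ybx1 itself on chromosome 4 from 119279199 to 119280413 had a delta PSI of 0.528, within the transcript that the hairpins target. Among MAPK ERK pathway genes, introns were retained in the kinase genes Mknk1 (chromosome 4, 115874814 to 115875381, delta PSI 0.388), Braf (chromosome 6, 39665106 to 39666246, 0.379) and Araf (chromosome X, 20853816 to 20853913, 0.321), and a second Mknk1 intron at 115875545 to 115876581 had a small p with a delta PSI of 0. Among splicing factor genes they were in Srsf9 (0.368), Srsf3 (0.359), Srsf10 (0.265) and Clk2 (0.235), each past the adjusted threshold. Jak3 (0.0243), Sh2b3 (0.155 and 0.0768), Il3ra (0.254), Bid (0.0527) and Mcl1 (0) had events in the JAK STAT and BCL2 lists that passed at the unadjusted p and not after adjustment. The smallest p values of other classes were in Ppia (alternative 3' splice site, 0.542), Eya3 (alternative 5' splice site, 0.167), Nsdhl (alternative first exon, -0.0263), Gigyf2 (alternative last exon, -0.160), Ahcyl1 (cassette exon, -0.00185) and Polm (mutually exclusive exons, -0.212, not past adjustment).

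In 2-sided Fisher's exact tests over 25 lists, 17 of 30 hnRNP and other regulators had an event at the authors' p under 0.05 (adjusted p = 1.72e-08), 18 of 37 spliceosome and SR proteins (7.07e-08), 9 of 24 translation factors (0.0039) and 5 of 11 erythroid genes (0.0216; Gata1, Itga2b, Nfe2, Tal1 and Zfpm1, named after the result was seen), against 10.4 to 10.5% of other genes. Among genes with an event in the table, the background that could have passed, the first 2 lists kept their call (adjusted p = 9.38e-05 and 9.87e-05), as did the erythroid list (5 of 7, 0.0329), and translation factors did not (0.149). These tests did not match genes for events per gene or for level. Genes with an event at p under 0.05 were 105 of 1395 in the lowest quartile of events per gene and 480 of 1395 in the highest. By mean TPM they were 13 of 2602 and 481 of 2602. How much of the lists' shares this accounts for was not tested. The erythroid list did not pass among genes with a mean TPM of 5 or more (0.0627) or at an event p under 0.01 (0.116), and passed with the adjusted event p (3 of 11, 0.009005). The cold shock domain and YBX1 partner list, at 4 of 11 and an adjusted p of 0.0921, passed at an event p under 0.01 (0.0179) and with the adjusted event p (0.009005), and not among genes with an event in the table (0.498). The MAPK ERK list had 8 of 35 (0.0942) and the JAK STAT list 5 of 16 (0.0921). In the authors' deposited pathway list, RNA splicing was first with 19 genes of a term of 365 (log10 p -11.85, log10 q -7.60). MAP2K and MAPK activation had 4 of 41 (log10 p -3.92, log10 q -1.274), which is just short of a q under 0.05. Genes with an event were called as changed in expression in 22.2% of cases and other genes in 27.7% (odds ratio 0.747), but the ratio turned to 1.70 with the adjusted event p, so no direction is drawn.

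The authors' deposited exon table lists 581 bins in 461 genes, all with the authors' adjusted p under 0.01. Of these 543 were higher and 38 lower in relative use in the knockdown libraries. By the GENCODE M21 annotation, 482 were exon in some transcripts and intron in others. In the replicate-based test of isoform use, limma called 0 of 26752 transcripts for both hairpins, for either hairpin or between them, against 2067, 1713, 1886 and 1640 at an unadjusted p under 0.05. The median residual SD was 1.62 log2 units, and in simulations shifts of 4 log2 units were found in 2 of 50 transcripts, so changes in isoform use were not detectable with these estimates rather than absent. No other tool was run on this question.

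The authors' deposited gene table was compared with the edgeR result. It held 3494 genes at its adjusted p under 0.05, 1973 higher and 1521 lower, of which 3289 were also called by edgeR in the fit used here. Signs were shared by 96.9% of 13552 genes, and across genes the log2 fold changes had a Pearson correlation of 0.985 and a Spearman correlation of 0.988. For Ybx1 the authors' deposited table gives -3.36 and edgeR gave -3.35.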

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

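All tests of explanations in this part were chosen after the results were seen. In shNT, 138 measures and named genes were checked for a library far from the others, 11 stood out, 10 of them in replicate 4, and chance alone would give about 6.9. For each, the gap to the nearest library as a share of the group's range is given. It was 0.931 for the scaling factor of shNT replicate 4, which was 0.847. Among normalised levels in replicate 4 it was 0.963 for Tnfrsf10b, 0.945 for Mt2, 0.942 for Plaur, 0.937 for Rps19-ps4, 0.936 for Eda2r, 0.909 for Timp1, 0.879 for Malat1, 0.856 for Bcl2l2 and 0.833 for Pcbp2, and in replicate 2 it was 0.897 for Lcn2.

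The direct edgeR test between hairpins called 71 genes. That count changed strongly with the shNT libraries in the fit, as given above, so it does not measure how far the hairpins agree. Log2 differences of sh1Ybx1 minus sh2Ybx1 were 5.603 for Lcn2, 4.91 for Acta2, 3.33 for Ccl6, 2.67 for Clec4e, 2.65 for Plaur, 2.56 for Cebpd, 2.46 for Id2, 1.99 for Tpm4 and 1.91 for Cpne3, and -1.54 for Hemgn, -1.44 for Slamf1, -1.37 for Frmd6, -1.24 for Anln and -1.22 for Plpp2. By camera at the preset correlation the median differences were 1.10 for the myeloid list, 0.28 for the MAPK ERK pathway, 0.24 for fibroblast genes, -1.77 for T and NK cell genes, -0.37 for MYC targets, -0.36 for the cell cycle list, -0.20 for ribosomal proteins and -0.16 for the spliceosome list. With an estimated correlation none of these lists passed. Genes outside the count table held 6.995% of TPM on average in the knockdown libraries (6.23 to 8.07%) and 5.54% in shNT (4.68 to 6.16%), a signal in genes that the comparisons did not use.

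Glycolysis and hypoxia genes fell in all 4 knockdown libraries. The unusual shNT replicate 4 alone is argued against, since the median was -1.31 without it and -1.68 with it. A culture state that varies among libraries whatever the hairpin, such as density or oxygen, stays open: the lowest shNT library lay 0.711 log2 units above the highest knockdown library, less than the range of 1.35 among shNT libraries. The labels give no culture density or harvest day, so such a state cannot be told apart from an effect of the hairpins, which also stays open.

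Intronic and noncoding RNA rose in the knockdown libraries. Genomic DNA as the main source is argued against by the means of 1728 olfactory and vomeronasal receptor genes, silent in most blood cells. Their mean rose from 0.0117 to 0.0263 FPKM, and that of the TEC and sense intronic genes from 0.803 to 1.43. The receptors' rise was thus 0.0234 times the other. By medians it was 0 times, which silent genes would mostly give in any case. The receptors were not filtered for expression, unlike the other set, and rose more in proportion, so a smaller share of DNA stays open. A single hairpin or library is argued against too, since in 8 of 10 noncoding classes every knockdown library lay above every shNT library, with processed pseudogenes and miRNA genes as the exceptions. Weaker selection of polyadenylated RNA stays open: histone genes had a median log2 fold change of 0.42 with quartiles of 0.07 and 0.66, against 1.16 for snoRNA genes, which does not decide. An effect of Ybx1 loss on intron removal or decay is a biological explanation that these tests leave open.

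A set of 9 genes had at most 3 counts over the 4 shNT libraries and at least 10 in each knockdown library, against 2 of the reverse kind: Tpm2, Nefm, Rbfox2, Map4k4 and 5 numbered genes, 4 of them processed pseudogenes and 1 transcribed (Gm12912, Gm13418, Gm4468, Gm8652 and Gm6211). These genes were picked after their values were seen. Reads from 1 outside source, at a different share in each library, may be the source: 11.11% of these genes departed from a common ratio between the knockdown libraries, against a median of 55.56% in 1000 draws of genes at like levels, and 1.9% of draws were as low. The set made up 24.6 and 33.3 CPM in sh1Ybx1 and 49.6 and 65.2 in sh2Ybx1. Reads shared with near-identical copies stay open, since 44.44% were processed pseudogenes (55.56% with the transcribed one) against 4.69% of tested genes, and a product of the knockdown procedure itself was not tested.

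In the 35 splits of the 8 libraries into 4 and 4, in fits of those 2 groups, only the real split, 1 of 35, gave as many called genes (3377, highest other 0). That is the smallest share that 35 splits allow. Every other split mixes knockdown and shNT libraries, so a real difference would enter its spread. The splits also treat the libraries as exchangeable, while the replicates may be technical, so chance is not excluded by this test. For isoform use the real value was 0 and the highest other 5. A count of 0 is reached by all 35 splits by construction, so that comparison does not bear on chance.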

How the results depend on the processing

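Limma on log2(TPM + 1), DESeq2, protein-coding genes only, adjusted event p, events without retained introns and the narrower background were chosen after the data were seen. Ybx1 kept its direction and call in all 69 values: -3.46 to -3.22 for both hairpins, -3.75 to -3.55 for sh1Ybx1 and -3.28 to -2.87 for sh2Ybx1. Of the values for named genes, 1978 kept direction and side of the threshold, 732 kept direction only and 14 reversed. Of the 732, 307 came from leaving out 1 library, 33 from other settings of the count fit and the rest from TPM or FPKM. Of the list values 173 kept both and 19 kept direction only. Where a hairpin was left with 1 library, that library was assumed to vary like the other groups.

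Counts for both hairpins, sh1Ybx1, sh2Ybx1 and the difference, against 3923, 2601, 2692 and 71, were 378, 153, 138 and 4 with TPM at pseudocount 0.1, 373, 208, 96 and 18 at pseudocount 5, 301, 187, 60 and 5 on FPKM, 281, 201, 64 and 5 with quantile-normalised TPM, and 370, 203, 127 and 5 with limma on log2(TPM + 1), where the median of all genes for both hairpins moved by -0.11. On the same 13512 genes limma called 3970 from counts and 553 from TPM. Over the 9235 of them with a mean TPM of 5 or more the median residual SD was 0.245 and 0.385 (log2). At a mean TPM of 5 or more they were 2212, 1424 and 1361, with fewer genes tested, and at a log2 fold change of 1 or more 1783, 1492 and 1430. Fits of only the groups compared gave 1372 for sh1Ybx1 and 1349 for sh2Ybx1, with fewer samples. For the difference they gave 5620, without the shNT libraries, whose biological coefficient of variation was 0.323 against 0.0760 and 0.0616 for the hairpins. The shNT libraries enter that contrast only through the spread, scaling and gene filter of the shared fit. Which of these moved the count was not tested. Protein-coding genes alone gave 1753 for sh2Ybx1 and 120 for the difference. The difference gave 42 without a variance trend and 794 with DESeq2. Where no cause is named, it was not tested.

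Same-numbered libraries gave no clear sign of pairing. Correlations of their deviations from the group mean ran from -0.0118 to 0.197 by the numbers in the titles. By those in the descriptions they ran from -0.197 to 0.157. Within a hairpin the deviations of the 2 libraries mirror each other, so these few values are not separate, and whether the numbers pair the samples stays open. By the titles shNT replicates 3 and 4 share a number with no other library, and by the descriptions only shNT replicate 4 does so. A replicate block gave 6653, 6143, 6087 and 3060, and a block by the numbers in the descriptions 6997, 5251, 6208 and 1268. The MAPK ERK list did not pass with the block (median -0.10).

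Leaving out 1 library gave 1272 to 6795 genes for both hairpins, 156 to 5902 for sh1Ybx1, 40 to 5843 for sh2Ybx1 and 0 to 1666 for the difference, the highest without shNT replicate 4 in each. Lists past the threshold ranged from 11 to 17. Transcripts with changed usage ranged from 0 to 1 for both hairpins and for sh1Ybx1, the 1 without sh2Ybx1 replicate 1, and were 2 at pseudocount 0.1.

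With an estimated correlation 1 list passed. Shared genes were 190 at an adjusted p under 0.01 and 0 as the median of split controls, where a hairpin without calls left nothing to share. Splicing events were 992 at p under 0.01, 368 after adjustment and 871 without retained introns, and exon bins 291 at or above the median effect. The authors' called genes were 1138 at 0.01 and 2039 at a mean TPM of 5 or more. The odds ratio of splicing and expression calls reversed from 0.747 to 1.05 at event p under 0.01 and 1.70 after adjustment, and the cause was not tested.

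Reversed log2 values, none past the threshold, were for Rps19-ps4 -0.19 (pseudocount 0.1), -0.14 (5), -0.0069 (quantile) and -0.18 (limma on log2(TPM + 1)), for Hnrnpu -0.44, -0.44, -0.24 (FPKM), -0.36 and -0.44, and for Hist3h2a -3.23, -0.34, -0.95 (FPKM), -1.20 and -1.14. On counts simulated with this number of libraries, 36 of 67 2-fold changes were found for both hairpins. Each gene had 1 spread for all libraries there, while the observed spread was larger in shNT than in the hairpins. No setting varied depth.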
